A study of Mus musculus with 28 samples.

How the data were processed

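The deposited values used were 2 tables of gene counts, unnormalised whole numbers per the labels, for 28 libraries of mouse primary microglia prepared with a QuantSeq 3′ forward kit after a column RNA extraction. The tables held 22 libraries (untreated and tau) and 11 libraries (untreated and amyloid), with 5 untreated libraries in both and identical there, and each library was used once. Per the submitters' processing notes the genome was GRCm38 (mm10) and DESeq2 1.38.3 was run on the counts; the aligner and the counting program are not given in the sources used here. Each table listed 60976 genes, of which 6360 held no number for any library and 25 had no name. Among the listed entries, 81 exact repeats and 108 further entries that shared a symbol were left out, and 3 symbols were set aside as ambiguous. This left 54424 entries, of which 29063 had a count above 0 in some library and 28779 of those had a symbol in GENCODE M21, which supplied coordinates. In all, 21 symbols had been turned into dates and were not used as gene names.

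Library totals ran from 14.5 M to 27.2 M counts (mean 19.0 M, SD 3.82 M, n = 28), with 17300 to 20020 genes detected. The 10 most abundant genes took 11.1 to 16.0% of counts and mitochondrial transcripts 0.934 to 1.79%. No 2 libraries were identical among 378 pairs, and the mean squared difference over its counting variance was 4.22 to 147 for the 57 pairs within a group. Library titles follow 2 naming series: the SAN title series (17 libraries, all treatments, 16.8 ± 1.25 M counts) and a second title series (11 libraries, untreated and tau, 22.5 ± 3.88 M counts). Replicates are numbered here within a group in order of title, so that untreated APOE3 libraries 1 to 3 and tau libraries 4 to 6 are of the SAN title series.

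Group, treatment and genotype were taken from the labels, where untreated libraries read Control, APOE3 libraries WT and APOE3S/S libraries Christchurch. The 11 comparisons, all alternatives but 2, the gene lists and the rule for naming genes were fixed before the data were examined. The gene lists were tested without APOE3S/S amyloid library 3 only after the results were seen. Tau contrasts used 22 libraries with a term for each group and 1 for title series, and the amyloid contrasts used the 11 libraries of untreated and amyloid-treated cells in the SAN title series. Tau against amyloid used all 17 SAN libraries. Genes were kept by filterByExpr by group, which left 13904, 13866 and 14117 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood F tests (glmQLFit, glmQLFTest), with Benjamini-Hochberg adjustment over all genes tested and a call at an adjusted p under 0.05. Values written ± are standard errors of log2 fold changes from that fit, or SD where group means in CPM (counts per M counts of the library, with M for 1e6) are given. Each error and each floor for a gene at 0 counts covers counting error or the spread between these libraries only.

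Named genes were chosen by rule: the 8 highest and 8 lowest called log2 fold changes with a mean of at least 5 CPM, the 3 smallest p-values in each list that passed, the 3 smallest in the interferon, cGAS-STING, inflammatory, disease-associated and homeostatic lists in each comparison, and 9 genes set beforehand (Apoe, Mb21d1, Tmem173, Ifnb1, Irf7, Isg15, Cxcl10, Tnf and Il1b). Mb21d1 and Tmem173 are the symbols used here for the genes of cGAS and STING. Genes quoted outside that rule are named as such.

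In all, 28 fixed lists were written from general knowledge: interferon-stimulated genes, cGAS-STING components, inflammatory cytokines with NF-kB targets, disease-associated and homeostatic microglia genes, MHC class I and class II presentation, cholesterol biosynthesis, LXR targets, lysosome and phagocytosis, complement, glycolysis, oxidative phosphorylation, cell cycle, NRF2 targets, unfolded protein response, alternative activation, receptors and heparan sulfate enzymes for APOE and tau, immediate-early genes, heat shock, ribosomal proteins, mitochondrial transcripts, and markers of astrocytes, oligodendrocytes, neurons, fibroblasts, border-associated macrophages with monocytes, and granulocytes with lymphocytes. The last had fewer than 5 tested members and was not tested. Lists were tested by camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Each was tested again with an estimated correlation and by fry (limma 3.58.1). Within each list the gene p-values were also adjusted over the list alone. For list scores (mean log2 CPM of the members), exact permutation tests exchanged libraries within a title series. Exact p-values are given without adjustment over the lists, unlike those of camera.

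Alternatives were RLE scaling, no low-count filter, a filter at 10 CPM, DESeq2 1.42.0, limma-voom, removal of each library in turn, each title series alone, no title-series term, a fit of the 2 compared groups alone, and for amyloid a fit of all 17 SAN libraries. Spiked log2 changes of 1 and 2 in simulated counts were recovered by edgeR at rates of 95 and 100% in tau against untreated APOE3, 79 and 100% for amyloid in APOE3, and 29 to 35 and 93 to 97% for the amyloid interaction. The simulation changed only genes with a mean of at least 5 CPM. It drew each gene and library independently, without stray libraries, so these rates need not hold for the real libraries. Software was R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Raw reads were not used here, so variants, isoforms and reads shared between gene copies were not analysed here.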

Results

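The 28 libraries held cultured primary mouse microglia of 2 APOE genotypes, APOE3 (labelled WT) and the homozygous Christchurch variant (APOE3S/S, labelled Christchurch). The cells were controls or had been given tau or amyloid. Untreated is the name used here for libraries whose treatment label reads Control, and that label does not say whether the cells received a vehicle. APOE3 groups had 6 untreated, 6 tau and 3 amyloid libraries, and APOE3S/S groups had 4, 6 and 3. Library titles followed 2 naming series, the SAN title series (17 libraries) and a second title series (11 libraries, untreated and tau). Values within each are given beside some of the pooled ones. Pooled values given without them need not hold to the same degree in both series. Values after gene names are log2 fold changes ± standard error unless CPM is written. The labels do not say whether replicates were separate cultures or animals, and the p-values measure the spread between these samples, which may be technical. Apoe (chromosome 7:19696109–19699188), whose product carries lipids, was found at 7.54 to 21.3 CPM (counts scaled to library size) per library, and 3′ tags check nothing of its genotype. Here and below, Apoe values count the mouse gene. Whether they hold the transcripts of the APOE3 or APOE3S/S allele was not tested.

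Tau raised interferon-stimulated and inflammatory genes in APOE3 microglia and lowered more disease-associated microglia genes than it raised, although none of the 3 lists passed with an estimated correlation (adjusted p = 0.16 each). Isg15 (chromosome 4:156199424–156200818), a ubiquitin-like modifier made in response to interferon, rose from 35.3 ± 15.5 CPM (n = 6) to 224 ± 95.2 CPM (n = 6), a log2 fold change of 2.53 ± 0.49 (adjusted p = 0.0013). Cxcl10 (chromosome 5:92346638–92348889), which draws T cells, rose by 3.99 ± 0.66 (adjusted p = 0.0004), and Il1b (chromosome 2:129364570–129371139), the gene of a cytokine processed by inflammasomes, by 2.72 ± 0.43 (adjusted p = 0.0003). Trem2 (chromosome 17:48346401–48354147), a receptor for lipids and APOE, fell by 0.90 ± 0.15 (adjusted p = 0.00039). In the SAN title series the changes were larger for Isg15 (3.81 against 1.68 in the second series), Cxcl10 (5.24 against 3.06), Il1b (3.88 against 1.69) and Trem2 (−1.33 against −0.44).

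**Figure D1:**
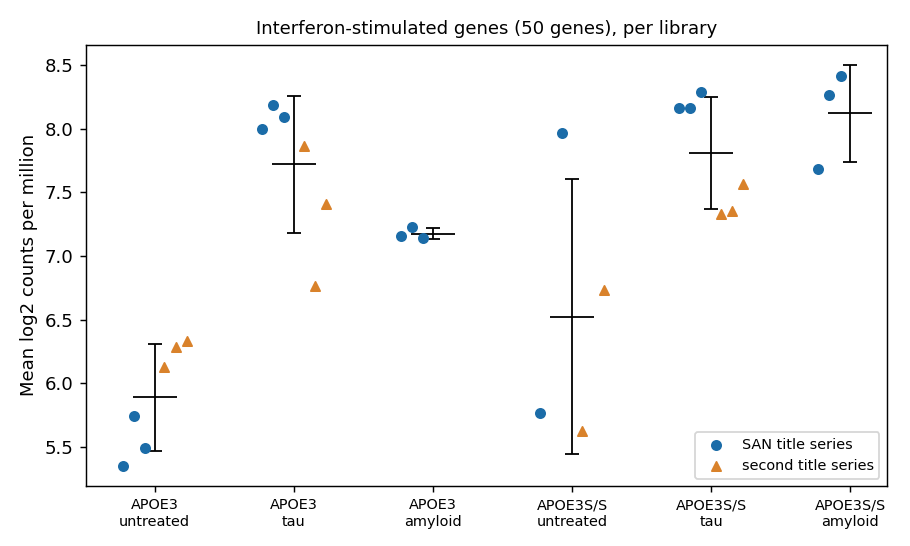
Mean log2 CPM of the 50 interferon-stimulated genes in each library, by genotype and treatment (x axis), with group mean and SD and the title series marked. Untreated APOE3 libraries averaged 5.89 ± 0.42 and tau libraries 7.72 ± 0.54, while the 4 untreated APOE3S/S libraries spread by 1.08 (SD).

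Of 13904 genes tested in tau against untreated APOE3, 1248 rose and 816 fell, and 606 of the changes exceeded 2-fold. DESeq2 called 2450 genes and limma-voom 2070, and within a title series edgeR called 2619 (SAN) and 372 (second). Besides that of Cxcl10, the largest rises were those of Ly6c2 (4.74 ± 0.70), a surface protein of monocytes (chromosome 15:75108158–75111970), Car4 (4.08 ± 0.86), a carbonic anhydrase, and Slfn4 (3.72 ± 0.54). Next came Cfb (3.68 ± 0.50), a protease of the alternative complement pathway, Ly6i (3.60 ± 0.55), Apol9b (3.52 ± 0.54) and Acod1 (3.37 ± 0.60), which makes itaconate. Car4 rose by 5.05 in the SAN title series and stood at 0.07 in the second. The largest falls were those of Slco2b1 (−2.52 ± 0.56), an organic anion transporter, Mamdc2 (−2.45 ± 0.36), Hpgd (−2.17 ± 0.43), which degrades prostaglandins, Rasgrp3 (−1.99 ± 0.37), Pde1c (−1.73 ± 0.38), Rnase4 (−1.61 ± 0.29), the purinergic-type receptor Gpr34 (−1.47 ± 0.38) and AF529169 (−1.47 ± 0.39). Slco2b1 stood at −3.89 and Pde1c at −3.03 in the SAN title series, against −0.80 and −0.705 in the second. Of 59 called genes named for this comparison 56 kept their call without any 1 library, and all 59 had the same sign in each title series. They were called in the pooled fit of both series, which favours a shared sign, so this is no test of agreement between the series. Over all 14612 genes tested for it, the log2 fold changes of the 2 series correlated at 0.38.

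All 50 tested interferon-stimulated genes rose with tau in APOE3 cells (50 also when adjusted over the list alone, median log2 fold change 1.61, camera adjusted p = 1.1e-37). The list did not pass with an estimated correlation (adjusted p = 0.16), and its score rose by 2.56 in the SAN title series and 1.10 in the second (exact p = 0.005). Examples were the RNA sensor gene Ddx58 (1.54 ± 0.25), the guanylate-binding protein gene Gbp3 (2.25 ± 0.37), the deISGylase gene Usp18 (2.12 ± 0.35) and Irf7 (2.05 ± 0.41), the transcription factor that amplifies type I interferon. Ifnb1 (chromosome 4:88522025–88522774), the gene of interferon beta, had 0 counts in all 6 untreated APOE3 libraries and 46 counts over the 6 tau libraries (0 to 17 each). That is 14.3-fold higher against a floor of 3 counts over the untreated group, without the counting error of the 46. Of 18 components of the cGAS-STING pathway 11 rose and 2 fell (12 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.00015, adjusted p = 0.16 with an estimated correlation), and the median stayed at 0.39 with Ifnb1 at that value. Zbp1 and Ifi204 belong to this list and to the interferon list, so that the lists are not separate evidence. Among them were the nucleic-acid sensor Zbp1 (2.18 ± 0.41), the nucleotide hydrolase Samhd1 (0.96 ± 0.18), the kinase Ikbke (0.98 ± 0.19) and Mb21d1 (0.74 ± 0.19, adjusted p = 0.012), which encodes cGAS. Tmem173 (chromosome 18:35733679–35740554), the gene of STING, rose by 0.42 ± 0.13 (adjusted p = 0.026), by 0.81 in the SAN title series and 0.05 in the second. The Tmem173 call was lost without untreated library 1, 2 or 3 (adjusted p = 0.062, 0.055 and 0.075) or tau library 4, 5 or 6 (0.059, 0.077 and 0.066).

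Inflammatory genes rose as a group: 29 of 36 were called, all upward (31 adjusted over the list alone, median 1.33, camera adjusted p = 6.2e-21, adjusted p = 0.16 with an estimated correlation). Besides Il1b they included Birc3 (1.05 ± 0.17), an inhibitor of cell death induced by NF-kB, and the list score rose by 2.62 in the SAN title series and 0.68 in the second (exact p = 0.01). Tnf, a main inflammatory cytokine, was not called (0.87 ± 0.31, adjusted p = 0.063; 1.94 and −0.03 by series). In the list of 21 MHC class I presentation genes 16 rose (16 adjusted over the list alone, median 0.79, camera adjusted p = 5e-10, adjusted p = 0.22 with an estimated correlation), among them the regulator Nlrc5 (1.19 ± 0.21), H2-T22 (1.36 ± 0.26) and Tapbp (1.09 ± 0.21). Of 9 MHC class II genes 5 rose (median 0.50, camera adjusted p = 0.0056, adjusted p = 0.21 with an estimated correlation). H2-Ab1 stood at 2.04 ± 0.54 (3.59 and 0.87 by series) and the co-stimulatory gene Cd86 at 0.55 ± 0.10. Complement genes gave 4 rises and no falls among 13 (6 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.041, adjusted p = 0.43 with an estimated correlation), including C3 (1.82 ± 0.33) and C1rl (1.81 ± 0.27).

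Genes of resident and disease-associated microglia split in direction. Of 27 disease-associated genes 3 rose and 12 fell (6 and 14 adjusted over the list alone, median −0.33, camera adjusted p = 0.00017, adjusted p = 0.16 with an estimated correlation), including Trem2, the pyrophosphate transporter gene Ank (−0.71 ± 0.10) and the growth factor gene Igf1 (−0.63 ± 0.10). Of 21 homeostatic genes 5 rose and 6 fell (5 and 9 adjusted over the list alone) and the list did not pass in 1 direction (median −0.31, camera adjusted p = 0.16), while fry without regard to direction gave an adjusted p of 2.3e-06. Gpr34 fell, whereas P2ry12, a purinergic receptor, rose by 0.89 ± 0.15. Gpr84, a fatty-acid receptor on the list as fixed, rose by 2.10 ± 0.36, and whether it marks resting cells was not tested. LXR targets and lipid genes gave 2 rises and 7 falls among 23 (3 and 11 adjusted over the list alone, median −0.27, camera adjusted p = 0.013, adjusted p = 0.16 with an estimated correlation), with Pparg (−1.42 ± 0.23), a nuclear receptor for lipids, and the lipoprotein lipase gene Lpl (−0.77 ± 0.13). Cholesterol biosynthesis gave 6 falls and no rises among 24 (7 falls adjusted over the list alone, median −0.19, camera adjusted p = 0.011, adjusted p = 0.54 with an estimated correlation), including Hmgcs1 (−0.44 ± 0.11) and Dhcr7 (−0.33 ± 0.09), whose call was lost without untreated library 1 (adjusted p = 0.060).

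**Figure D2:**
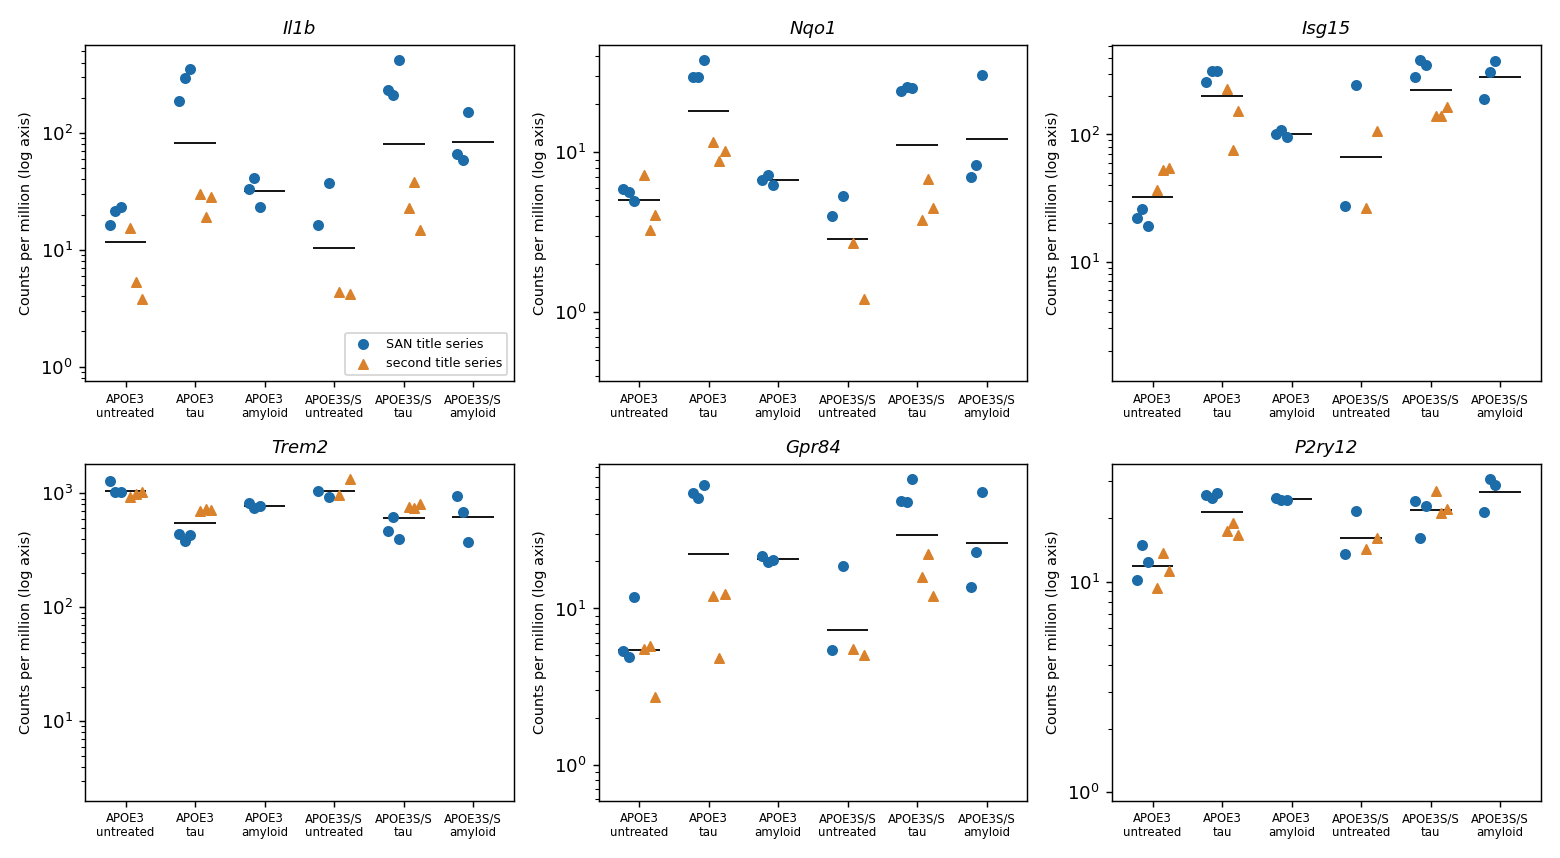
CPM of Il1b, Nqo1, Isg15, Trem2, Gpr84 and P2ry12 per library on log axes, by group, with the geometric mean and the title series marked. Il1b averaged 14.3 CPM in untreated and 153 CPM in tau-treated APOE3 libraries, while Trem2 averaged 1046 and 568 CPM.

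Further lists passed camera, among them those of stress and metabolic genes. NRF2 targets gave 5 rises and 1 fall among 20 (7 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 0.00064, adjusted p = 0.40 with an estimated correlation). Nqo1 (chromosome 8:107388225–107403206), a quinone reductase, stood at 1.80 ± 0.31, the cystine transporter gene Slc7a11 at 1.66 ± 0.35 and Prdx6 at 0.76 ± 0.13. The unfolded protein response gave 8 rises and 2 falls among 24 (median 0.20, adjusted p = 0.002 by camera and 0.27 with an estimated correlation). Pdia4 stood at 0.64 ± 0.11 and Atf3, a stress-induced repressor, at −1.04 ± 0.16. Glycolysis gave 6 rises among 23 (9 and 1 fall adjusted over the list alone, median 0.23, adjusted p = 0.0021 by camera and 0.30 with an estimated correlation). Pfkl stood at 0.57 ± 0.11 and Hk2 at 0.43 ± 0.09. Alternative activation (6 rises, 1 fall of 14, median 0.31, camera adjusted p = 0.013, adjusted p = 0.16 with an estimated correlation) held Tgm2 (1.00 ± 0.18) and the cytokine-signalling suppressor Socs1 (2.15 ± 0.41). Receptors and heparan sulfate enzymes for APOE and tau (7 rises of 20, median 0.22, camera adjusted p = 0.013, adjusted p = 0.38 with an estimated correlation) held the sorting receptor gene Sorl1 (0.89 ± 0.14) and Agrn (1.49 ± 0.25), a heparan sulfate proteoglycan. Markers of border-associated macrophages and monocytes (6 rises and 1 fall of 17, median 0.24, camera adjusted p = 0.0056, adjusted p = 0.16 with an estimated correlation) held Vcan (2.19 ± 0.36), a matrix proteoglycan.

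Ribosomal protein genes stood lower with tau (2 falls of 28, 0 adjusted over the list alone, median −0.23, camera adjusted p = 8.3e-05, adjusted p = 0.54 with an estimated correlation). Rpl3 fell by 0.34 ± 0.10, and its call was lost without untreated library 1 (adjusted p = 0.059). Cell-cycle genes gave 2 falls of 30 (median −0.17, camera adjusted p = 0.047, adjusted p = 0.65 with an estimated correlation), Pcna (−0.50 ± 0.09) and Stmn1 (−0.90 ± 0.20), and their score differed in sign by series (0.14 and −0.47). The other lists did not pass in tau against untreated APOE3: oxidative phosphorylation (27 genes, median 0.07, camera adjusted p = 0.079) and lysosome and phagocytosis (29 genes, 4 rises and 7 falls, median −0.04, adjusted p = 0.26). The same held for immediate-early genes (20 genes, 1 rise and 4 falls, adjusted p = 0.36), heat shock (14 genes, 1 fall, adjusted p = 0.36) and mitochondrial transcripts (14 genes, adjusted p = 0.92). Nor did markers of fibroblasts (14 genes, 3 rises and 2 falls, adjusted p = 0.29), astrocytes (12 genes, 1 rise, adjusted p = 0.49), neurons (6 genes, no call, adjusted p = 0.49) or oligodendrocytes (15 genes, 1 rise, adjusted p = 0.67). Apoe itself was not called (−0.21 ± 0.19, adjusted p = 0.55) and differed in sign by series (−0.64 and 0.26).

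Tau in APOE3S/S microglia raised some inflammatory genes and lowered some disease-associated microglia genes. Neither list passed with an estimated correlation (adjusted p = 0.32 each), and most calls depended on single libraries. Il1b rose by 3.06 ± 0.50 (n = 6 tau and 4 untreated, adjusted p = 0.005), by 3.49 and 2.51 in the SAN and second title series, and Nqo1 by 2.01 ± 0.37 (adjusted p = 0.0087; 2.49 and 1.34). Trem2 fell by 0.78 ± 0.16 (adjusted p = 0.015; −0.94 and −0.63). Cxcl10 rose by 2.52 ± 0.66 (adjusted p = 0.039; 2.25 and 3.38). Not called were Isg15 (1.24 ± 0.53, adjusted p = 0.19; 1.35 and 1.06), Irf7 (0.93 ± 0.45, adjusted p = 0.26), Tnf (0.88 ± 0.35, adjusted p = 0.16), Mb21d1 (0.48 ± 0.22, adjusted p = 0.22), Tmem173 (0.20 ± 0.14, adjusted p = 0.47) and Apoe (−0.30 ± 0.21, adjusted p = 0.46).

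In APOE3S/S 296 genes rose and 159 fell of 13904, with 153 beyond 2-fold; DESeq2 called 950 and limma-voom 697, and edgeR called 638 in the SAN title series and 330 in the second. Besides that of Il1b, the largest rises were of Serpinb2 (3.98 ± 0.79), a protease inhibitor of activated macrophages, the receptor gene Tarm1 (3.82 ± 0.84), the neutrophil chemokine gene Cxcl3 (3.42 ± 0.64), Acod1 (2.96 ± 0.67), Slc6a12 (2.89 ± 0.57), the prostaglandin E synthase gene Ptges (2.71 ± 0.56) and H2-M2 (2.61 ± 0.67). Hpgd (−1.72 ± 0.46), Rasgrp3 (−1.67 ± 0.40), Mamdc2 (−1.59 ± 0.38), Efr3b (−1.33 ± 0.34), the sialic-acid receptor gene Siglecf (−1.22 ± 0.20), Gm1673 (−1.19 ± 0.29), Lsp1 (−1.15 ± 0.27) and Rnase4 (−1.15 ± 0.30) fell most. Without untreated library 1 the count fell to 34, without untreated library 3 to 261 and library 4 to 302, without tau library 2 to 249, tau library 4 to 134 and tau library 6 to 91, and without untreated library 2 it was 836. Of the 41 called genes named for this comparison, only Il1b, Hk2 and Siglecf kept their call without any 1 library. Of the others, 38 lost it without untreated library 1, 27 without tau library 6, 23 without tau library 4, 20 and 17 without untreated libraries 3 and 4, 11 without tau library 2, 4, 3 and 2 without tau libraries 5, 1 and 3, and 1 without untreated library 2.

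Interferon-stimulated genes had a median of 0.97 with tau in APOE3S/S: 7 of 50 rose and 42 did when adjusted over the list alone (camera adjusted p = 4.9e-27, adjusted p = 0.32 with an estimated correlation, score rises of 1.34 and 1.23 by series, exact p = 0.01). The median was 1.62 without untreated library 2 and 0.74 without untreated library 1. Among the 7 were the ADP-ribosyltransferase gene Parp14 (0.90 ± 0.22), Ddx58 (1.11 ± 0.28) and Slfn8 (1.01 ± 0.26). Inflammatory genes gave 20 rises of 36 (31 adjusted over the list alone, median 1.18, camera adjusted p = 3.2e-22, adjusted p = 0.32 with an estimated correlation). Birc3 stood at 1.00 ± 0.19. The cGAS-STING list had no called member (8 up and 1 down adjusted over the list alone, median 0.27, camera adjusted p = 0.0038, adjusted p = 0.34 with an estimated correlation). Trim56 stood at 0.45 ± 0.13 (adjusted p = 0.057), Ikbke at 0.71 ± 0.21 (adjusted p = 0.068) and Enpp1, which degrades cGAMP, at −0.92 ± 0.30 (adjusted p = 0.088). Disease-associated genes gave 9 falls and no rise of 27 (14 and 1 adjusted over the list alone, median −0.30, camera adjusted p = 5.8e-05, adjusted p = 0.32 with an estimated correlation). Lpl stood at −0.74 ± 0.14 and Ank at −0.50 ± 0.11. The homeostatic list gave 1 rise and 1 fall (5 and 6 adjusted over the list alone, median −0.20, camera adjusted p = 0.21). The rise was that of Gpr84 (1.93 ± 0.40), whose place on the list was fixed beforehand and not tested. Fcrls stood at −0.76 ± 0.21 (adjusted p = 0.05, not called).

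Of the remaining lists in APOE3S/S with tau, 11 passed camera and none of them with an estimated correlation. MHC class I stood higher (median 0.36, 2 rises, 9 adjusted over the list alone, adjusted p = 0.34 with an estimated correlation), and Nlrc5 rose by 0.91 ± 0.23 and the peptide trimmer gene Erap1 by 0.46 ± 0.12. Glycolysis (median 0.30, adjusted p = 0.32 with an estimated correlation) held Hk2 (0.59 ± 0.10). NRF2 targets (median 0.34, adjusted p = 0.34 with an estimated correlation) held Slc7a11 (2.00 ± 0.41) and Prdx6 (0.72 ± 0.15). Unfolded protein response (median 0.18), receptors and enzymes for APOE and tau (0.24) and fibroblast markers (1.02) were also higher, each with an adjusted p of 0.34 with an estimated correlation. Pdia4 rose by 0.52 ± 0.12, Atf3 fell by 0.75 ± 0.17, Sorl1 rose by 0.70 ± 0.16, Agrn by 1.10 ± 0.28 and, in the fibroblast list, the receptor gene Pdgfrb by 2.43 ± 0.61. Lower were ribosomal proteins (median −0.32; Rpl3 −0.39 ± 0.11) and cell cycle (−0.39; Pcna −0.43 ± 0.10, Stmn1 −0.88 ± 0.22), each with an adjusted p of 0.34 with an estimated correlation. Cholesterol biosynthesis (−0.21) and mitochondrial transcripts (−0.17) had an adjusted p of 0.53 and LXR targets (−0.22) of 0.32 in the same test. In the LXR list Pparg fell by 1.09 ± 0.25, and the fatty-acid ligase gene Acsl1 rose (2.09 and 0.65 in the 2 title series).

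The tau responses of the 2 genotypes shared direction: 427 genes were called in both, 281 up and 146 down (26.6 and 9.33 expected by chance), and none in opposite directions. Of the genes called in APOE3, 98.5% had the same sign in APOE3S/S. Tested directly, the difference between the tau responses gave no gene by edgeR (284 at an unadjusted p under 0.05, 695 expected). DESeq2 and limma-voom also gave 0, as did edgeR in either title series. Fewer genes than expected stood at an unadjusted p under 0.05, so that the absence of calls is no evidence that the genotypes respond alike. The difference was −1.29 ± 0.68 for Isg15 (95% interval −2.71 to 0.13), −1.47 ± 0.89 for Cxcl10, −1.13 ± 0.59 for Irf7, −3.02 ± 0.89 for Ly6c2, −1.09 ± 0.58 for Zbp1, −0.44 ± 0.22 for P2ry12, 0.34 ± 0.61 for Il1b, −0.25 ± 0.29 for Mb21d1, −0.23 ± 0.19 for Tmem173 and −0.10 ± 0.29 for Apoe, each with an adjusted p of 1. The Cxcl10 difference stood at −2.99 in the SAN title series and 0.32 in the second. All 50 interferon-stimulated genes had a smaller estimate in APOE3S/S (median −0.67, camera adjusted p = 2.3e-10, adjusted p = 0.89 with an estimated correlation). That median was −0.12 (adjusted p = 0.43) without untreated APOE3S/S library 2 and −0.02 in the second title series alone. Without untreated APOE3S/S libraries 2 and 4, a choice made after the results were seen, it was 0.29 (camera adjusted p = 1.3e-05). Both were chosen for high interferon-stimulated genes, which by itself moves the median upward, so that this p-value is no test.

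With tau, no interferon-stimulated or inflammatory gene was called between APOE3S/S and APOE3 microglia when both title series were fitted together. Isg15 stood at 244 ± 111 and 224 ± 95.2 CPM (n = 6 each, log2 difference 0.09 ± 0.45, 95% interval −0.84 to 1.03), Cxcl10 differed by 0.19 ± 0.52 (−0.89 to 1.27) and Irf7 by 0.13 ± 0.39. The intervals do not exclude a 2-fold difference. Other differences were those of Il1b (0.01 ± 0.38), Tnf (−0.26 ± 0.30), Mb21d1 (−0.04 ± 0.19), Tmem173 (−0.07 ± 0.13), Trem2 (0.16 ± 0.15), Tnfaip3 (−0.23 ± 0.13) and Apoe (0.10 ± 0.19). Each of these genes had an adjusted p of 1. The interferon list had a median of 0.06 (camera adjusted p = 0.16, score difference 0.09, exact p = 0.64), and it was −0.06 without APOE3 tau library 2 and −0.00 without APOE3S/S tau library 6. The inflammatory list had a median of −0.06 (camera adjusted p = 0.43). By edgeR 2 genes were called, and 300 had an unadjusted p under 0.05 against 695 expected. DESeq2 and limma-voom called 3 each, and edgeR called 2 in the SAN title series and 8 in the second. The fit held 1 additive term for title series, although the tau response differed between the series in 748 genes in APOE3. Such differences enter the spread, so that few calls are no evidence that the genotypes are alike. The 8 held the sex-linked Xist, Ddx3y, Eif2s3y and Kdm5d, which follow the sex difference of that series, and the inflammatory gene Il1rn, Cx3cr1 and Vcan beside Gm47283. Gm47283 (chromosome Y:90784738–90816464), a predicted gene, was higher in APOE3S/S by 3.99 ± 0.38 (adjusted p = 6.7e-06; 4.11 and 3.83 by series). Gm4779 (chromosome X:101790053–101794423) was lower, at 0.0397 against 0.661 CPM; it lies outside the naming rule and was chosen after its values were seen. Only 1 gene was called without APOE3 tau library 1 or APOE3S/S tau library 1, 2, 3 or 6, and 3 were without APOE3 tau library 3, and Gm47283 was called in each.

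Cholesterol biosynthesis genes all stood higher in tau-treated APOE3S/S cells, 24 of 24, without any member called (median 0.24, camera adjusted p = 4.6e-21, adjusted p = 0.077 with an estimated correlation, score differences of 0.32 and 0.21 by series, exact p = 0.01 without adjustment over the lists). Among their smallest p-values were those of Tm7sf2 (0.36 ± 0.12) and Lss (0.28 ± 0.10), enzymes of the later pathway (adjusted p = 1 each). NRF2 targets stood lower in 17 of 20 (median −0.16, camera adjusted p = 3.3e-05, adjusted p = 0.50 with an estimated correlation). Nqo1 stood at −0.63 ± 0.28 and Cat at −0.23 ± 0.09. Homeostatic genes stood higher in 19 of 21 (median 0.07, camera adjusted p = 0.045, adjusted p = 0.50 with an estimated correlation), but their score differed in sign by series (−0.09 and 0.33), as did Cx3cr1, the fractalkine receptor gene (−0.14 and 0.93). Mitochondrial transcripts (−0.18), neuron markers (0.28) and complement (0.05) also passed camera, and with an estimated correlation their adjusted p were 0.50, 0.12 and 0.50.

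**Figure D3:**
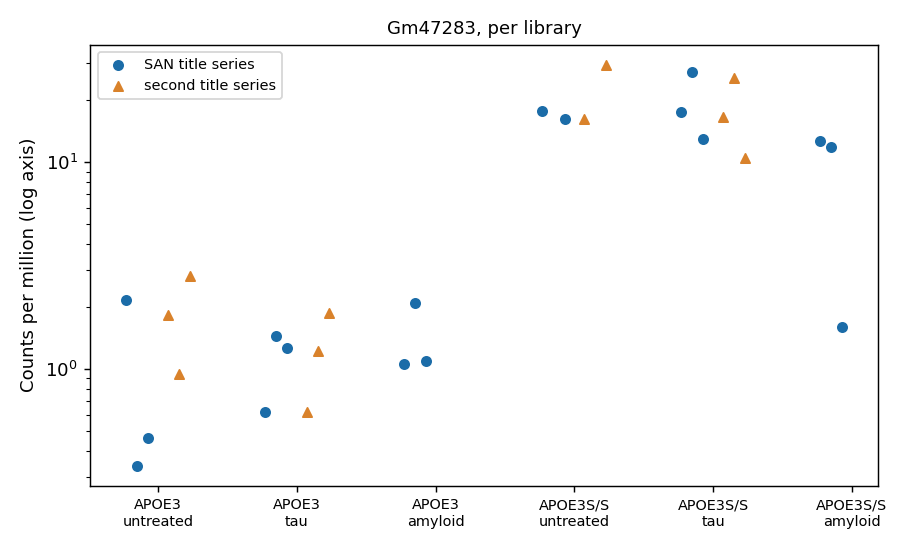
CPM of Gm47283 per library on a log axis, by group, with the title series marked. All but 1 of the APOE3S/S libraries lay above 10 CPM and all APOE3 libraries below 3 CPM; APOE3S/S amyloid library 3 lay at 1.59 CPM.

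In untreated cells the genotypes differed in 1 gene, Gm47283 (3.83 ± 0.39, n = 4 and 6, adjusted p = 2.3e-05). It stood at 16.9 against 0.987 CPM in the SAN title series, where it was not called, and at 22.9 against 1.86 CPM in the second. Interferon-stimulated genes stood higher in untreated APOE3S/S, 50 of 50 (median 0.72, camera adjusted p = 2e-14, adjusted p = 0.63 with an estimated correlation). Isg15 stood at 102 ± 103 against 35.3 ± 15.5 CPM (95% interval of the log2 difference 0.31 to 2.45, adjusted p = 0.64). Cxcl10 differed by 1.66 ± 0.73, Irf7 by 1.26 ± 0.44 and the synthetase-like Oasl1 by 1.64 ± 0.56, and no member was called. P2ry12 differed by 0.48 ± 0.16, also without a call. The score differed by 1.33 in the SAN title series and −0.07 in the second (exact p = 0.28), and the median fell to 0.17 without APOE3S/S library 2. Without APOE3S/S libraries 2 and 4, chosen after the results were seen for high interferon-stimulated genes, the median was −0.24. Ifnb1 had 23 counts in the 4 APOE3S/S libraries, 19 of them in library 4, against 0 in APOE3. That is 10.3-fold higher against a floor of 3 counts over the APOE3 group, without the counting error of the 23. Mb21d1 (0.21 ± 0.22), Tmem173 (0.16 ± 0.14), Il1b (−0.34 ± 0.47), Tnf (−0.27 ± 0.35) and Apoe (0.20 ± 0.21) were not called. In all, 1077 genes had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 3, and edgeR 0 in the SAN title series and 4 in the second, of which 3 were the sex-linked Xist, Ddx3y and Eif2s3y. The count was 5 without APOE3S/S library 1 and 2 without APOE3S/S library 3 or APOE3 library 3 or 6.

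Besides interferon, 9 lists passed camera in untreated cells, each with an adjusted p of 0.63 with an estimated correlation. Cholesterol biosynthesis was higher in 24 of 24 genes (median 0.18, 3 called over the list alone). Acat2 stood at 0.62 ± 0.15 and Mvk at 0.54 ± 0.14. Complement was higher in 13 of 13 (0.34, 4 called over the list alone). C1qb stood at 0.41 ± 0.15. MHC class I was higher in 20 of 21 (0.32). The immunoproteasome gene Psmb8 stood at 0.53 ± 0.22. Ribosomal proteins (0.17), oxidative phosphorylation (0.16), cell cycle (0.22), border-associated macrophage markers (0.26) and cGAS-STING components (0.16) were higher and NRF2 targets (−0.14) lower. Some ribosomal and interferon-stimulated genes also lead a component that parts untreated libraries within each genotype, as given below. The medians of those lists therefore need not follow genotype. In the second title series, Xist, the transcript of the inactive X, stood at 0 to 0.629 CPM in APOE3S/S libraries and 336 to 530 CPM in APOE3 libraries, so that sex and genotype changed together there, whereas the SAN libraries all held Xist (79.5 to 312 CPM).

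With amyloid in APOE3 microglia edgeR called no gene in the fit of 11 libraries, 131 in a fit of all 17 SAN libraries and 575 in a fit of the 2 groups alone. The interferon-stimulated genes stood higher without passing as a list under an estimated correlation (adjusted p = 0.61). Isg15 stood at 102 ± 6.81 CPM with amyloid (n = 3) and 22.5 ± 3.42 CPM untreated (n = 3), a log2 difference of 2.17 ± 0.58 (adjusted p = 0.21). Irf7 differed by 1.98 ± 0.48 (adjusted p = 0.21), Cxcl10 by 2.74 ± 0.94 (adjusted p = 0.27), Oasl2 by 1.84 ± 0.37, Ifi213 by 2.58 ± 0.53 and Slfn5 by 1.42 ± 0.29. All 50 interferon genes were higher, none called over all genes and 50 over the list alone (median 1.54, camera adjusted p = 3.4e-32, adjusted p = 0.61 with an estimated correlation; score difference 1.64, exact p = 0.1, the smallest that 3 against 3 can give). Ifnb1 had 12 counts over the 3 amyloid libraries and 0 untreated, 3.63-fold higher against the same floor, without the counting error of the 12. In the fit of 11 libraries 0 of 13866 genes were called (smallest adjusted p 0.212, 1823 genes at an unadjusted p under 0.05 with 693 expected), 289 by DESeq2 and 0 by limma-voom. Leaving out untreated library 3 gave 1.

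Other groups moved less with amyloid in APOE3. Inflammatory genes were higher in 30 of 36 (median 0.55, camera adjusted p = 1.8e-05, adjusted p = 0.63 with an estimated correlation). Marco, a scavenger receptor, stood at 1.30 ± 0.36, Il1b at 0.67 ± 0.39 (adjusted p = 0.48) and Tnf at 0.63 ± 0.39. Cell-cycle genes were higher in 27 of 30 (14 over the list alone, median 0.54, adjusted p = 0.61 with an estimated correlation), among them Tk1 (0.85 ± 0.20), Rrm2 (1.17 ± 0.31) and Top2a (0.81 ± 0.21). Components of cGAS-STING (8 over the list alone, median 0.35, adjusted p = 0.61 with an estimated correlation) held Zbp1 (2.09 ± 0.51), Mb21d1 (0.74 ± 0.25) and Tmem173 (0.47 ± 0.16). Disease-associated genes stood lower (median −0.25, adjusted p = 0.63 with an estimated correlation). The protease gene Ctsd stood at −0.55 ± 0.18 and the galectin gene Lgals3 at −0.74 ± 0.25, although Axl stood at 0.55 ± 0.18. Homeostatic genes did not pass (median 0.14, camera adjusted p = 0.061, 4 over the list alone). Cx3cr1 stood at 0.98 ± 0.15 (adjusted p = 0.21), P2ry12 at 0.97 ± 0.20 and Csf1r at 0.51 ± 0.14. MHC class I (0.44), receptors for APOE and tau (0.21; Sorl1 0.88 ± 0.21, Agrn 1.48 ± 0.32), border-associated macrophage markers (0.39), complement (0.15; C3 1.56 ± 0.39) and cholesterol (0.11) also stood higher, and ribosomal proteins (−0.24) and NRF2 targets (−0.18) lower. With an estimated correlation the adjusted p of these lists was 0.61 to 0.68. Apoe stood at −0.13 ± 0.23.

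In APOE3S/S, amyloid (n = 3) against untreated cells (n = 2) gave 0 of 13866 genes by edgeR (smallest adjusted p 0.582; 1181 at an unadjusted p under 0.05; 2 by DESeq2 and 0 by limma-voom). Among inflammatory genes Il6, the gene of an acute-phase cytokine, differed by 3.53 ± 0.73, Il1b by 1.81 ± 0.46, the receptor antagonist gene Il1rn by 1.60 ± 0.50 (adjusted p = 0.58 each) and Tnf by 0.88 ± 0.44. In all, 34 of 36 were higher (2 over the list alone, median 0.95, camera adjusted p = 8.2e-14, adjusted p = 0.45 with an estimated correlation). Without amyloid library 3, which lay nearest to APOE3 tau, the median was 0.47, Il6 differed by 2.79, Il1b by 1.26, Il1rn by 0.86 and Tnf by 0.34. Cxcl10 then stood at 0.67, Nqo1 at 0.78, Prdx1 at 0.46, Cst7 at 0.89, Ch25h at 0.71 and Apoe at −0.12. Interferon-stimulated genes were higher in 50 of 50 (median 0.80, camera adjusted p = 2.3e-22, adjusted p = 0.45 with an estimated correlation). Isg15 stood at 1.11 ± 0.63, Cxcl10 at 1.41 ± 0.87, Irf7 at 0.82 ± 0.53, Trim30a at 0.74 ± 0.28 and Usp18 at 1.10 ± 0.46. Cholesterol genes were lower in 23 of 24 (median −0.46, camera adjusted p = 1.9e-07, adjusted p = 0.45 with an estimated correlation). Lss stood at −0.58 ± 0.17, Hmgcs1 at −0.65 ± 0.21 and Hsd17b7 at −0.72 ± 0.23. MHC class I (0.47), class II (0.29), cGAS-STING (0.23; Mb21d1 0.47 ± 0.28, Tmem173 0.48 ± 0.18), oxidative phosphorylation (0.17; Cycs 0.66 ± 0.16), NRF2 (0.31; Nqo1 1.76 ± 0.54, Prdx1 0.91 ± 0.33), unfolded protein (0.24), border-associated macrophage (0.47), heat shock (0.16) and glycolysis (0.16) lists passed camera upward. With an estimated correlation their adjusted p was 0.45 to 0.56. Without amyloid library 3 the NRF2 (0.08) and glycolysis (0.09) lists no longer passed camera (adjusted p = 0.51 and 0.14), and the heat shock median was 0.09 and that of cGAS-STING 0.14. Complement (0.30), cell cycle (0.14) and ribosomal proteins (0.14) then passed camera upward (adjusted p = 0.62, 0.76 and 0.76 with an estimated correlation). Homeostatic and disease-associated genes did not pass (camera adjusted p = 0.43 and 0.19), with P2ry12 at 0.66 ± 0.22, P2ry13 at 1.01 ± 0.31, Cst7 at 1.98 ± 0.77 and Ch25h at 1.58 ± 0.56, and Apoe stood at −0.39 ± 0.26. Without untreated library 2 edgeR called 425 genes and the interferon median was 2.06, and without untreated library 1 it was 0.19 (adjusted p = 0.16).

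**Figure D4:**
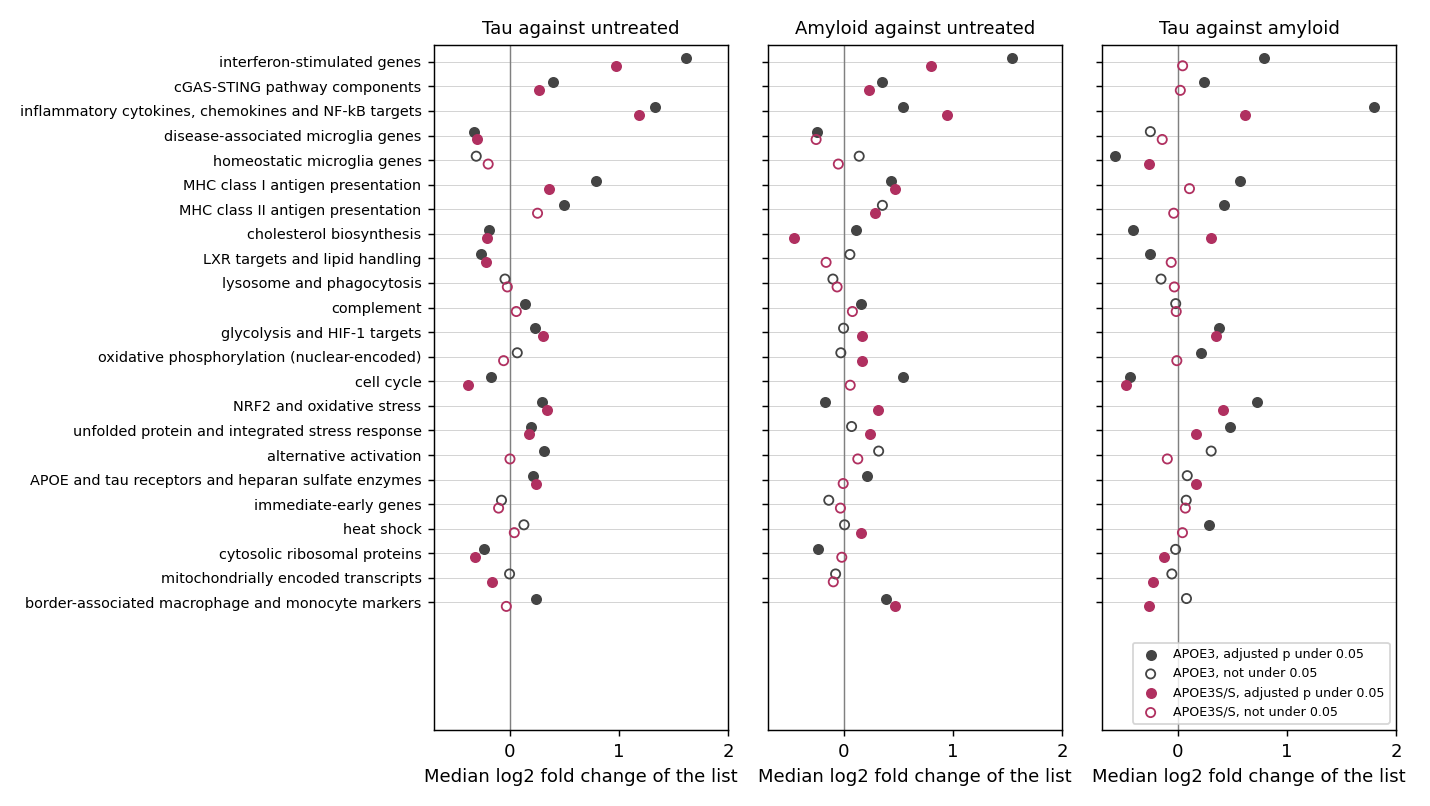
Median log2 fold change (x axis) of 23 gene lists in tau against untreated, amyloid against untreated and tau against amyloid, in APOE3 (grey) and APOE3S/S (red), with filled points where camera gave an adjusted p under 0.05. The interferon-stimulated list lay at 1.61 and 0.97 with tau and at 1.54 and 0.80 with amyloid, and at 0.79 and 0.04 in tau against amyloid.

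Between the genotypes with amyloid (n = 3 each) edgeR called 0 genes (smallest adjusted p 0.30; 1673 at an unadjusted p under 0.05; 59 by DESeq2, 0 by limma-voom and 352 in a fit of the 2 groups alone). Interferon-stimulated genes stood higher in APOE3S/S in 50 of 50 (median 0.89, camera adjusted p = 2.8e-14, adjusted p = 0.46 with an estimated correlation; exact p = 0.1, the smallest possible). Isg15 stood at 293 ± 95.9 against 102 ± 6.81 CPM (1.61 ± 0.56, adjusted p = 0.39). Cxcl10 differed by 2.23 ± 0.78, the monocyte chemokine gene Ccl12 by 2.95 ± 0.76, Usp18 by 1.31 ± 0.41, Irf7 by 1.13 ± 0.47 and Ifi204 by 0.88 ± 0.28. Inflammatory genes did so in 36 of 36 (10 over the list alone, median 0.85, camera adjusted p = 6.6e-09, adjusted p = 0.46 with an estimated correlation). Il6 stood at 3.54 ± 0.61, Ccl4 at 1.16 ± 0.23 (adjusted p = 0.30 each), Ccl2 at 2.74 ± 0.61 and Il1b at 1.59 ± 0.39. Without APOE3S/S amyloid library 3, which lay nearest to APOE3 tau, 26 of 35 inflammatory genes stood higher, with a median of 0.29. Il6 then stood at 2.80, Il1b at 1.03, Cxcl10 at 1.48, Tnf at −0.05 and Apoe at 0.21, and the interferon median was 0.75. Cholesterol genes stood lower in 23 of 24 (median −0.42, camera adjusted p = 8.6e-09, adjusted p = 0.46 with an estimated correlation). Lss stood at −0.53 ± 0.15, Dhcr7 at −0.40 ± 0.12 and Hmgcs1 at −0.58 ± 0.19. Homeostatic genes stood lower in 16 of 21 (−0.22, adjusted p = 0.29 with an estimated correlation). Gpr34 stood at −1.09 ± 0.36. Fibroblast markers stood lower in 11 of 15 (−0.89, 6 over the list alone). The collagen gene Col1a1 stood at 0.232 ± 0.15 against 8.20 ± 7.56 CPM. Further lists past camera upward were MHC class I (0.56) and II (0.30; Cd74 0.77 ± 0.22, Cd86 0.51 ± 0.10), oxidative phosphorylation (0.25; Cycs 0.67 ± 0.14), glycolysis (0.13; Pgk1 0.52 ± 0.13, Pkm 0.44 ± 0.12), unfolded protein (0.28), complement (0.32), heat shock (0.14), cGAS-STING (0.19), ribosomal (0.16), immediate-early (0.29) and NRF2 (0.26). Oligodendrocyte markers (−0.85) passed downward. Without library 3 NRF2 targets had a median of −0.00 (camera adjusted p = 0.64), and MHC class II, cGAS-STING, heat shock and oligodendrocyte lists also lost the pass (camera adjusted p = 0.061, 0.11, 0.11 and 0.051). Glycolysis then stood at 0.08, ribosomal proteins at 0.31 and fibroblast markers at −1.41, and disease-associated genes (0.16) passed camera (adjusted p = 0.51 with an estimated correlation). With an estimated correlation the adjusted p of these lists was 0.46 to 0.68. Mb21d1 (0.41 ± 0.25), Tmem173 (0.25 ± 0.16), Tnf (0.50 ± 0.38) and Apoe (−0.06 ± 0.24) were among the genes not called.

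The difference between the amyloid responses of the genotypes gave 0 genes by edgeR, DESeq2 and limma-voom (514 at an unadjusted p under 0.05, 693 expected, smallest adjusted p 0.938). Cholesterol genes had a median of −0.61 (camera adjusted p = 1.4e-10, adjusted p = 0.76 with an estimated correlation). Lss stood at −0.78 ± 0.23. Isg15 stood at −1.05 ± 0.83, Cxcl10 at −1.33 ± 1.26, Irf7 at −1.16 ± 0.69, Oasl2 at −1.26 ± 0.53, Cx3cr1 at −0.89 ± 0.22, Il1b at 1.14 ± 0.59, Il6 at 3.38 ± 1.11, Nqo1 at 1.49 ± 0.70, Atf4 at 0.56 ± 0.22 and Apoe at −0.26 ± 0.35. Without APOE3S/S amyloid library 3, Nqo1 stood at 0.52, Il1b at 0.60, Il6 at 2.65, Cxcl10 at −2.06 and Apoe at 0.02, and the cholesterol median was −0.46. The interferon median of −0.64 (camera adjusted p = 0.0055, adjusted p = 0.84 with an estimated correlation) became 0.66 without untreated APOE3S/S library 2, −1.29 without untreated APOE3S/S library 1 and −0.54 (adjusted p = 0.23) without APOE3S/S amyloid library 1. Leaving out untreated APOE3S/S library 1 also gave 3 called genes.

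Compared directly within the SAN title series, tau left APOE3 microglia with more of some cytokine, NRF2 and glycolysis transcripts than amyloid did. The 3 lists did not pass with an estimated correlation (adjusted p = 0.18, 0.18 and 0.17). Il1b was higher by 3.20 ± 0.42 (n = 3 each, adjusted p = 0.0025), Il6 by 4.80 ± 0.62 (adjusted p = 0.0025) and Il1a by 1.89 ± 0.29. Nqo1 was higher by 2.36 ± 0.39 (adjusted p = 0.0059) and the glucose transporter gene Slc2a1 by 0.98 ± 0.15 (adjusted p = 0.0042). Of 14117 genes 610 were higher and 443 lower with tau, 391 beyond 2-fold (1597 by DESeq2, 1078 by limma-voom). Besides Il6, the largest differences upward were Cxcl3 (4.67 ± 0.82), Serpinb2 (4.65 ± 1.04), the signalling adaptor gene Traf1 (4.17 ± 0.85), Tarm1 (4.01 ± 0.81), Slc6a12 (3.41 ± 0.54), the siderophore-binding Lcn2 (3.30 ± 0.68) and Car4 (3.23 ± 0.58). Downward they were Slco2b1 (−2.84 ± 0.54), Rasgrp3 (−2.47 ± 0.49), Mamdc2 (−2.26 ± 0.45), Hpgd (−2.21 ± 0.51), Pde1c (−2.03 ± 0.47), Rtn4rl1 (−1.93 ± 0.38), Gpr34 (−1.84 ± 0.35) and Adamts1 (−1.73 ± 0.33). The count was 58 without tau library 6, 572 without tau library 4, 191 without tau library 5, and 202, 218 and 141 without amyloid libraries 1, 2 and 3. Of 43 called genes named here 11 kept their call without any 1 library, and 32 lost it without tau library 6.

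Among the lists for tau against amyloid in APOE3, inflammatory genes gave 29 higher of 36 (36 over the list alone, median 1.79, camera adjusted p = 3.9e-24, adjusted p = 0.18 with an estimated correlation). Tnf stood at 1.30 ± 0.33. NRF2 targets gave 13 of 20 (15 over the list alone, median 0.73, adjusted p = 0.18 with an estimated correlation). Gsr was higher by 0.92 ± 0.16 and Prdx1 by 1.43 ± 0.26. Glycolysis gave 9 of 23 (13 over the list alone, median 0.38, adjusted p = 0.17 with an estimated correlation). Pkm stood at 0.68 ± 0.10 and Pgk1 at 0.80 ± 0.12. Interferon-stimulated genes gave 5 of 50 (23 over the list alone, median 0.79, camera adjusted p = 2e-11, adjusted p = 0.46 with an estimated correlation). Cxcl10 was higher by 2.49 ± 0.66, Ccl12 by 2.59 ± 0.65, Usp18 by 1.30 ± 0.35 and Isg15 by 1.64 ± 0.48 (adjusted p = 0.0496). Irf7 (1.01 ± 0.40, adjusted p = 0.13), Mb21d1 (0.64 ± 0.22), Tmem173 (0.34 ± 0.14) and Apoe (−0.52 ± 0.24) were not called. Homeostatic genes gave 2 higher and 8 lower of 21 (median −0.58, camera adjusted p = 0.00024, adjusted p = 0.053 with an estimated correlation). MHC class I (median 0.57, 3 higher; Psme2 1.35 ± 0.35) and class II (0.42, 3 higher; H2-Ab1 2.55 ± 0.66), unfolded protein response (0.48, 7 higher and 1 lower; Pdia4 0.65 ± 0.13), oxidative phosphorylation (0.21, 2 higher; Cycs 0.92 ± 0.14), heat shock (0.28, 3 higher; Hspa1b 1.51 ± 0.39) and cGAS-STING (0.24, Enpp1 lower by 1.61 ± 0.30) passed camera upward. Their adjusted p were 0.32, 0.18, 0.18, 0.48, 0.23 and 0.48 with an estimated correlation. Cholesterol (−0.41, Dhcr7 lower by 0.40 ± 0.11), cell cycle (−0.44, 4 lower; Cenpf −1.27 ± 0.32, Plk1 −0.92 ± 0.26) and LXR targets (−0.25, 5 lower, 1 higher; Pparg −1.35 ± 0.32, Acsl1 1.97 ± 0.45) passed downward. With an estimated correlation their adjusted p were 0.42, 0.54 and 0.39. Disease-associated genes did not pass (2 higher, 2 lower of 27, median −0.25, camera adjusted p = 0.11). Ch25h stood at 2.13 ± 0.45 and Ank and Timp2 at −0.72 ± 0.13 and −0.67 ± 0.15.

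In APOE3S/S, tau against amyloid (n = 3 each) gave 10 higher and 11 lower genes (1325 at an unadjusted p under 0.05; 159 by DESeq2, 19 by limma-voom and 2 in a fit of the 2 groups alone). Gatm (chromosome 2:122594467–122611303), an enzyme of creatine synthesis, was lower by 1.23 ± 0.15 (adjusted p = 0.0082), the Fc receptor-like Fcrls, a microglial marker, by 0.93 ± 0.12 (adjusted p = 0.0089) and Fcrl1 by 1.72 ± 0.29. Also lower were Fam214a by 1.14 ± 0.20, the deacetylase gene Hdac9 by 1.07 ± 0.16, Cyp4f18 by 1.05 ± 0.18, the folate receptor gene Folr2 by 0.97 ± 0.17 and Cd244a by 0.87 ± 0.13. The lactate transporter gene Slc16a3 was higher by 0.73 ± 0.10 (adjusted p = 0.01), Ets2 by 1.21 ± 0.22 and the lipopolysaccharide co-receptor gene Cd14 by 1.14 ± 0.19. Also higher were Ier3 by 1.12 ± 0.18, Arg2 by 1.02 ± 0.18, Tgm2 by 0.97 ± 0.15, Maff by 0.96 ± 0.17, Ralgds by 0.88 ± 0.13 and Sdc4 by 0.71 ± 0.12. Glycolysis (median 0.35, 15 over the list alone, camera adjusted p = 3.8e-14) and homeostatic genes (median −0.26, 6 lower over the list alone, camera adjusted p = 0.0015) passed also with an estimated correlation, at an adjusted p just under 0.05. Without amyloid library 3, which lay nearest to APOE3 tau, neither did (adjusted p = 0.060 and 0.11 with an estimated correlation), whereas NRF2 targets did (0.045). Inflammatory genes passed camera alone (median 0.62, 9 over the list alone, camera adjusted p = 9.8e-16, adjusted p = 0.31 with an estimated correlation; median 1.04 without amyloid library 3). So did cell-cycle genes, lower in 30 of 30 (11 over the list alone, median −0.47, camera adjusted p = 4.8e-15, adjusted p = 0.25 with an estimated correlation). Il1b (1.66 ± 0.39, adjusted p = 0.14), Slc2a1 (0.60 ± 0.15), Cx3cr1 (−1.06 ± 0.21, adjusted p = 0.063), Isg15 (0.22 ± 0.47), Cxcl10 (0.83 ± 0.60), Irf7 (0.10 ± 0.39), Tnf (0.59 ± 0.32) and Apoe (−0.41 ± 0.25) were not called. Nor were Mb21d1 (0.06 ± 0.22), Tmem173 (−0.13 ± 0.14), Nfkb2 (0.64 ± 0.17), Cxcl2 (1.46 ± 0.40), Prdx6 (0.75 ± 0.16), Ccna2 (−1.25 ± 0.32) and Top2a (−0.86 ± 0.23). Without amyloid library 3, Il1b (2.23, adjusted p = 0.006), Slc2a1 (0.83), Cx3cr1 (−1.07), Tnf (1.14, adjusted p = 0.045), Nfkb2 (0.89), Cxcl2 (2.15), Prdx6 (1.02) and Ccna2 (−1.43) were called, and Cxcl10 stood at 1.59 and Apoe at −0.68 without a call. Whether tau against amyloid differs between the genotypes was not tested.

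NRF2 targets (median 0.41), cholesterol genes (0.30), receptors for APOE and tau (0.16), astrocyte markers (0.84) and the unfolded protein response (0.17) passed camera upward in that comparison, and mitochondrial transcripts (−0.23), border-associated macrophage markers (−0.26) and ribosomal proteins (−0.13) downward. With an estimated correlation their adjusted p were 0.25, 0.33, 0.61, 0.64, 0.61, 0.72, 0.31 and 0.92. The interferon list did not pass (31 higher and 19 lower, median 0.04, camera adjusted p = 0.62). Without amyloid library 3 the medians were 0.17 for interferon, 0.68 for NRF2, −0.24 for ribosomal and −0.40 for border-associated genes. Astrocyte markers (0.29) and mitochondrial transcripts then lost the pass (camera adjusted p = 0.46 and 0.098), and disease-associated genes (−0.27) and LXR targets (−0.17) gained it (0.0015 and 0.044; adjusted p = 0.34 and 0.40 with an estimated correlation). No gene was called without tau library 6, 1 and 2 were without amyloid libraries 1 and 2, 7 were without tau library 5 and 452 were without amyloid library 3. All 17 called genes named here lost the call without tau library 6, 16 and 15 without amyloid libraries 1 and 2, 11 without tau library 5 and 4 without tau library 4.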

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

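Every test in this part, other than the counts of genes over splits of the libraries and the gene list tests of the response differences, was chosen only after the results were seen: those of APOE3S/S amyloid library 3, of untreated APOE3S/S libraries 2 and 4, of Gm47283, and of tau responses between title series. Looking for a stray library in 64 sets of values found 4, and chance picks about 1 in 20 sets, so that 3.2 were expected.

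By root mean square log2 distance to group means, APOE3S/S amyloid library 2 lay nearest to its own label (0.162). Amyloid library 1 lay nearest to untreated APOE3S/S (0.261, against 0.332 to its own label). The library labelled APOE3S/S amyloid 3 lay nearest to a group of another treatment and genotype, and it also differed in Gm47283. Its log2 profile lay nearest to the mean of APOE3 tau libraries (root mean square distance 0.164, within the highest distance of an APOE3 tau library, 0.184), farther from APOE3S/S tau (0.224) and from its own label (0.360). The 3 APOE3S/S tau libraries of the SAN title series also lay nearest to APOE3 tau, so this distance speaks of treatment and not of genotype. Its Gm47283 level was 0.77 log2 CPM (27 counts), inside the APOE3 range (−1.21 to 1.59) and outside that of the other APOE3S/S libraries (3.44 to 4.98), although that gene was the only 1 of 14357 that parted the genotypes in the other 27 libraries. If Gm47283 marked the genotype of every culture, at most 14.0% of the RNA of this library could be APOE3S/S. That would argue against a mixture with at least 0.5 of APOE3S/S RNA. Gm47283 lies on chromosome Y, apart from Apoe, so it need not follow the APOE genotype. A swapped label may explain both values, and these counts do not settle it. A biological reading, a culture that responded to amyloid more strongly, would leave the Gm47283 level unexplained.

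Untreated APOE3S/S library 2 held Cxcl10 at 5.37 and Tnf at 4.68 log2 CPM, outside the other untreated APOE3S/S libraries (Cxcl10 0.59 to 1.34, Tnf 3.61 to 3.77), and had 17969 detected genes against 18785 to 18948. On the axis from untreated to amyloid it lay at 1.02, in the range of treated libraries (0.74 to 1.63) and outside that of other untreated ones (−0.09 to 0.45). That axis left out the interferon-stimulated, MHC class I and cGAS-STING lists. Its profile lay nearest to APOE3S/S amyloid (root mean square distance 0.211, against 0.490 to its own label). It may be a treated library or an untreated culture with an active response that reaches beyond those lists, and these values do not part the 2. Untreated library 4 also held a high interferon score (6.74 log2 CPM), but lay at −0.00113 on the tau axis, among the other untreated libraries (−0.11 to 0.33) and not the treated ones (0.51 to 1.11), which argues against a treated library. Without libraries 2 and 4 the interferon median in untreated APOE3S/S against APOE3 went from 0.72 to −0.24. A fall follows from the choice itself, since both were picked for high interferon-stimulated genes. Whether APOE3S/S raises these genes at rest therefore rests on those libraries.

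Gm47283 was higher in APOE3S/S libraries, and untreated library 4 stood above its group at 4.98 log2 CPM. A difference in the sexes of the cells is argued against, since in the tau libraries of the SAN title series Gm47283 differed by 4.01 log2 while the Y-linked Ddx3y differed by −0.51 and Xist by 0.52. Gm21887 (chromosome X:170009659–170019281), another predicted gene, differed by 1.97 with tau. Reads shared between near-identical copies or another copy number in the strain may account for both, and these counts cannot tell those apart from regulation.

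None of the 19 lists named here passed with an estimated correlation. Lists whose tau response differed between genotypes by camera had medians of −0.67 (interferon-stimulated), −0.28 (MHC class I), −0.15 (oxidative phosphorylation), −0.26 (cell cycle), −0.10 (ribosomal proteins), −0.14 (mitochondrial transcripts) and −0.27 (border-associated macrophages and monocytes). For the amyloid response the medians were −0.64 (interferon-stimulated), 0.21 (inflammatory), −0.26 (homeostatic), −0.61 (cholesterol), 0.16 (glycolysis), 0.20 (oxidative phosphorylation), −0.47 (cell cycle), 0.41 (NRF2), 0.29 (unfolded protein response), −0.30 (receptors and enzymes for APOE and tau), 0.26 (heat shock) and 0.22 (ribosomal proteins). Without APOE3S/S amyloid library 3 the inflammatory (−0.22), glycolysis (0.12) and unfolded protein (0.22) lists of the amyloid response no longer passed camera, and the medians of NRF2 and ribosomal genes were 0.24 and 0.39; disease-associated genes (0.23) then passed camera (adjusted p = 0.77 with an estimated correlation). Without untreated APOE3S/S library 2 the interferon medians were −0.12 for tau and 0.66 for amyloid, and without libraries 2 and 4 that for tau was 0.29. Libraries 2 and 4 were chosen for high interferon-stimulated genes, which by itself moves these medians upward. Between the title series the tau response differed in 748 genes in APOE3 and 133 in APOE3S/S.

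Splits of the same libraries into groups of the same sizes, exchanged within a title series, were drawn 100 times for the tau comparisons, the real split included. No other split drawn called as many genes for tau against untreated in APOE3 (2064 genes, highest other split 6, 1 of 100 as large). The same held for tau in APOE3S/S (455 genes, highest other 11, 1 of 100) and for APOE3S/S against APOE3 with tau (2 genes, highest other 0, 1 of 100). For these comparisons the splits argue against a chance assignment of these libraries. They say nothing of chance differences between cultures or animals, since the labels do not say whether replicates were separate. For the genotypes in untreated cells a chance assignment cannot be excluded (1 gene, highest other 2127, 7 of 100). For the difference of the tau responses the count was 0 genes, so that every split was as large (highest other 0, 100 of 100) and the splits say nothing of it. The split that called 2127 genes set untreated APOE3S/S libraries 2 and 4 with APOE3 libraries 1 and 6 against the rest, which points to a structure of the untreated samples that does not follow genotype. On the third principal component of all libraries (11.5% of the variance) they lay at 7.51, 39.4, 17.8 and 6.68, and the other untreated libraries at −16.9 to 1.46. Its leading genes held Rpl30-ps10, Rpl21, Rps27, Rps27a, Isg15 and Ccl2 on that side and Xist on the other. What causes this structure was not tested.

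For the comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. Amyloid against untreated in APOE3 gave 0 genes and 0 in the highest other split (10 of 10 as large), and the genotypes with amyloid gave 0 and 0 (10 of 10), so that the splits say nothing of either. Tau against amyloid gave 1053 genes in APOE3 with 0 in the highest other (1 of 10). In APOE3S/S it gave 21 genes with 79 in the highest other (2 of 10), a split that set amyloid libraries 1 and 2 and tau library 5 against amyloid library 3 and tau libraries 4 and 6.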

How the results depend on the processing

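Of the alternatives, 2 were chosen only after the results were seen, both of which leave out 2 APOE3S/S libraries. Over counts of called genes and list medians 347 alternatives were run, of which 244 left the result the same and 103 did not, 6 of them with a reversed sign, and the cause was not tested. Over the genes named in the text 4579 of 5431 values were the same, 852 were not. None changed sign with a call in either fit, although some genes called in neither fit did change sign. Without a low-count filter edgeR called 1441 genes for tau in APOE3S/S, 42 and 343 between genotypes with tau and untreated, 149 for the difference of the tau responses, 1008 and 665 for amyloid in APOE3 and APOE3S/S, 740 between genotypes with amyloid, 76 for the difference of the amyloid responses, and 1892 and 487 for tau against amyloid in APOE3 and APOE3S/S; the filter at 10 CPM left 1 gene between genotypes with tau. DESeq2 gave 950 for tau in APOE3S/S, 5 between untreated genotypes, 289, 2 and 59 for amyloid in APOE3, in APOE3S/S and between genotypes, and 1597 and 159 for tau against amyloid. Limma-voom gave 697 for tau in APOE3S/S and 3 between untreated genotypes. A fit of the 2 compared groups alone gave 262 for tau in APOE3S/S, 575 for amyloid in APOE3, 352 between genotypes with amyloid, and 3646 and 2 for tau against amyloid in APOE3 and APOE3S/S. Without a title-series term tau gave 846 in APOE3 and 0 in APOE3S/S. The second title series alone gave 372 for tau in APOE3, 8 between genotypes with tau and 4 untreated, and the SAN title series 0 untreated; a fit of all 17 SAN libraries gave 131 for amyloid in APOE3. In the second title series the interferon median was 0.00773 between untreated genotypes (adjusted p = 0.47 by camera) and −0.0171 for the difference of the tau responses (adjusted p = 0.23). Without untreated APOE3S/S libraries 2 and 4 tau gave 911 genes in APOE3S/S, and the interferon median became −0.24 between untreated genotypes (camera adjusted p = 0.00095) and 0.29 for the difference of the tau responses (camera adjusted p = 1.3e-05). Both libraries were chosen for high interferon-stimulated genes, so that removing either moves interferon medians by itself. Such p-values are therefore no test of genotype. Without untreated APOE3S/S library 2 and APOE3S/S amyloid library 3 the counts were 424 for amyloid in APOE3S/S, 43 between genotypes with amyloid and 660 for tau against amyloid in APOE3S/S, and the interferon median of the difference of the amyloid responses became 0.56 (adjusted p = 1.2e-09).

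Gene lists that passed camera numbered 17, 15, 6, 10 and 7 in the tau comparisons (tau in APOE3, in APOE3S/S, genotypes with tau, genotypes untreated, difference), 12, 12, 17 and 12 in the amyloid comparisons and 14 and 12 in tau against amyloid. With an estimated correlation they numbered 0 in all but tau against amyloid in APOE3S/S, where 2 remained, and both were lost without amyloid library 3 (glycolysis 0.060 and homeostatic genes 0.11). By fry they numbered 14, 6, 0, 0 and 0, then 0, 0, 1 and 0, then 8 and 2. Libraries of the 2 genotypes with the same title number gave no sign of pairing: 4 of 13 such pairs correlated above 0.1 (range −0.20 to 0.43), and in 4 of them the same number gave the best match. With a block for these numbers edgeR called 1 gene between genotypes with tau, 1 untreated, 0 with amyloid and 0 for either difference of responses.

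With 1 library left out in turn, the count for tau in APOE3 ran from 1548 to 2314, for tau in APOE3S/S from 34 (without untreated library 1) to 836 (without untreated library 2), between genotypes with tau from 1 to 3 and untreated from 1 to 5 (without APOE3S/S library 1). It was 0 throughout for the difference of the tau responses and between genotypes with amyloid. Amyloid gave 0 to 1 in APOE3 (1 without untreated library 3) and 0 to 425 in APOE3S/S (425 without untreated library 2), and the difference of the amyloid responses 0 to 3 (3 without untreated APOE3S/S library 1). Tau against amyloid ran from 58 (without tau library 6) to 572 (without tau library 4) in APOE3 and from 0 (without tau library 6) to 452 (without amyloid library 3) in APOE3S/S. The interferon median ran from 1.43 to 1.74 and 0.74 to 1.62 for tau in APOE3 and APOE3S/S, −0.0609 to 0.12 between genotypes with tau (negative without APOE3 tau library 2 and just under 0 without APOE3S/S tau library 6) and 0.17 (without APOE3S/S library 2) to 0.95 untreated. For the difference of the tau responses it ran from −0.89 to −0.12 (without untreated APOE3S/S library 2). With amyloid it ran from 1.41 to 1.64 in APOE3, 0.19 (without untreated library 1) to 2.06 (without library 2) in APOE3S/S and 0.75 to 1.01 between genotypes. For the difference of the amyloid responses it ran from −1.29 (without untreated APOE3S/S library 1) to 0.66 (without library 2).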

Other observations

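The comparison of tau responses between title series was chosen only after the results were seen. The median of cholesterol biosynthesis genes stood higher in APOE3S/S than in APOE3 in untreated cells (0.18, adjusted p = 0.63 with an estimated correlation) and with tau (0.24, adjusted p = 0.077). It stood lower with amyloid (−0.42, adjusted p = 0.46), and at −0.31 without APOE3S/S amyloid library 3, which lay nearest to APOE3 tau. In no genotype comparison was a cholesterol gene called over all genes. Within the SAN title series (n = 3 each), P2ry12, a purinergic receptor gene of resting microglia, stood at 12.5 ± 2.38 CPM untreated, 25.8 ± 0.686 with tau and 24.6 ± 0.227 with amyloid in APOE3.

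In the same series Ly6c2 stood at 5.40 ± 2.66 CPM in untreated APOE3 cells, 150 ± 21.1 with tau and 46.1 ± 9.45 with amyloid. Among all 28 libraries, the first principal component took 50.5% of the variance of 8871 genes. Ly6c2, Cxcl10, Acod1 and Il1b were among its leading genes on 1 side and Slco2b1, Hpgd, Mamdc2 and Gpr34 on the other.

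The tau response differed between title series. In APOE3, 748 of 14612 genes differed, 366 with a higher and 382 with a lower log2 fold change in the SAN title series, and Il1b rose by 3.85 there and by 1.70 in the second (adjusted p = 0.043 by edgeR). In APOE3S/S 133 genes differed, 75 and 58. The log2 fold changes of the 2 title series correlated at 0.38 in APOE3 and 0.20 in APOE3S/S. What parts the title series is not given in the sources used here.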
